A study of Arabidopsis thaliana with 24 samples.

How the data were processed

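Gene expression was measured by RNA sequencing in roots and shoots of 7-day-old Arabidopsis thaliana seedlings of 3 genotypes. Wild type (WT) is Col-0, pxy is the pxy-5 mutant of the receptor kinase gene PXY, and 41-OX expresses CLE41 constitutively. Each of the 6 groups of genotype and organ held 4 biological replicates, so there were 24 samples. Libraries followed, per the labels, a published high-throughput protocol by Kumar and colleagues. The submitters' processing notes name CASAVA, TopHat2 and HTSeq and the genome build TAIR10, without versions, annotation release or overlap mode.

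The deposited file holds raw read counts per locus, in the unit counts, with 1 column per sample. The design text names 2 technical replicates per sample, which the file does not hold apart, and whether they were pooled is not stated. Counts were used for 33602 loci, of which 32835 had a row in the reference annotation of TAIR10.1, from which gene names and positions were taken by locus code. HTSeq's summary lines were left out of the totals. Reads with no feature were 1.82% to 3.41% and ambiguous reads 1.80% to 2.61% of each library. The counts are per locus, so where reads fall within a gene could not be examined.

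The total was 7033091 to 12226066 counts in 23 libraries and 167131 in WT shoot replicate 2. Intervals and floors given below cover counting error only, since PCR copies are not independent molecules.

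Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, quasi-likelihood fit with robust dispersions and its F-test, two-sided). The 12 root and the 12 shoot libraries were fitted apart, each with 3 groups and no covariate. The contrasts were each mutant against WT and 41-OX against pxy. Whether an effect differed between organs was tested as a root-minus-shoot contrast in 1 fit of all 24 libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values below come from this test unless another is named. Fold changes are log2 values with their standard error (SE). Levels are TMM-normalised CPM, counts scaled to a common library total, given as mean ± SD over the n libraries of a group. Levels of organ-specific genes used CPM without TMM scaling.

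Genes changed in both genotypes were counted by direction. These counts were compared with 48 simulated sets of unchanged groups set against the same WT libraries, with the product of independent lists, and with each genotype set against 2 separate WT libraries.

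A total of 19 gene lists with 327 loci were fixed before the data were examined: TDIF-PXY pathway, vascular proliferation regulators, xylem and secondary wall, lignin biosynthesis, phloem, ethylene and ERF, auxin response, cytokinin response, brassinosteroid biosynthesis, cell cycle, jasmonate and wounding, salicylate defence, anthocyanin and flavonoid, heat and handling stress, circadian clock, photosynthetic tissue, root epidermis and uptake, endodermis and suberin, and stomatal lineage. The last 4 held markers of the other organ or of other cell types, and the TDIF-PXY list was chosen from earlier work on this pathway. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation preset at 0.01), two-sided, and adjusted over 76 tests of 19 lists in the 4 contrasts against WT. The medians given for lists are of edgeR's log2 fold changes unless log2 CPM is named. For each list the members passing over all genes and the members passing when p was adjusted over the list alone were counted.

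The genes named were taken by a rule fixed before the data were examined. PXY and CLE41 came first. For each contrast against WT, it took the 8 genes with the largest rise and the 8 with the largest fall among called genes with an average log2 CPM of at least 1 and no overlap between the groups. It also took up to 4 called members per list, up to 12 genes shared in opposite direction, and up to 5 genes in each direction for 41-OX against pxy and for the root-minus-shoot contrasts. Some genes the rule gave were left out of the text after their values were seen, and the text says where a gene was chosen after its values were seen.

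Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no low-count filter, at least 10 counts in every library of a group, the DESeq2 1.42.0 Wald test, a fold threshold of 1 on the log2 scale, a replicate block, other sets of libraries in the fit, and leaving out each replicate. The library labelled pxy root replicate 2 had the profile of a shoot. Groups were kept as labelled, and every root result was also computed without that library, which was chosen after seeing the data. For the same reason the tests of the full fits were also read for only the genes within 1.5-fold between organs, with p adjusted again over those tested. These were 19607 of the 33602 loci, counted before the low-count filter, so they include loci that were not tested. The procedure was tested on simulated data with known changes built from these libraries. Changed genes were drawn only from those with a mean of at least 10 counts. At 2-fold the test recovered 31.3% of changed genes for pxy roots as designed, 73.1% without the library labelled pxy root replicate 2, and 82.1% for pxy shoots. In the same order, 4 of 76, 10 of 150 and 18 of 183 called genes were unchanged ones, so false calls could exceed 5%.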

Results

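RNA was counted in roots and shoots of 7-day-old seedlings of WT, pxy and 41-OX, with 4 libraries in each of 6 groups. PXY is a receptor kinase of the procambium, the dividing tissue of the vascular bundle, and CLE41 encodes its peptide ligand TDIF. The series asks, per its title, which genes regulate vascular proliferation. Totals were 9496863 to 11631762 counts in WT roots, 7765685 to 9256266 in pxy roots and 8387529 to 12226066 in 41-OX roots. They were 7291630 to 8638785 in pxy shoots and 7033091 to 9025246 in 41-OX shoots. WT shoots held 7868951 to 11052295 counts in 3 libraries and 167131 in replicate 2.

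The library labelled pxy root replicate 2 had a shoot profile. Genes specific to shoots stood at 93.7% of the shoot mean in it, and genes specific to roots at 5.24% of the root mean. Across 21460 genes, its log2 levels correlated with those of shoot libraries at r = 0.976 to 0.988 and with those of root libraries at r = 0.687 to 0.803, where genes are not independent replicates. Root results are given as labelled and without this library. In 41-OX roots, replicate 4 held shoot-specific genes at 11.4% of the shoot mean. In 41-OX shoots, root-specific genes stood at 5.44% to 6.78% of the root mean. They stood at 0.702% to 1.43% in WT and pxy shoots other than WT shoot replicate 2, where the median root-specific gene had no count. Organ-specific genes were the 157 root and 385 shoot genes with at least 20 CPM in 1 organ and 50-fold less in the other. They were chosen on WT and pxy libraries without the library labelled pxy root replicate 2 and WT shoot replicate 2.

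**Figure D1:**
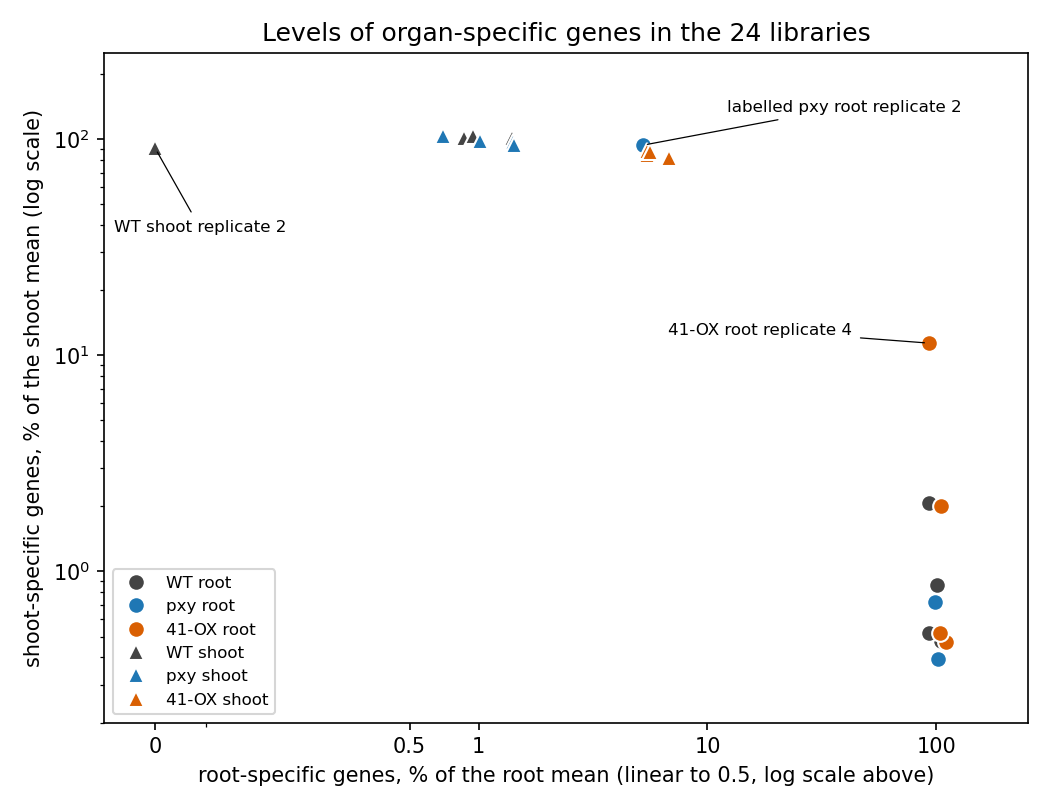
Median level of root-specific genes (horizontal, percent of the root mean, linear to 0.5 and log scale above) against shoot-specific genes (vertical, percent of the shoot mean, log scale), 1 point per library, circles for libraries labelled root and triangles for shoot. The library labelled pxy root replicate 2 sits with the shoots at 93.7% and 5.24%, and 41-OX shoots lie at 5.44% to 6.78% on the horizontal axis.

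CLE41 (AT3G24770, TAIR10.1 chromosome 3, 9046293 to 9047463, 1 exon) was higher in 41-OX in both organs. In roots it stood at 33.0 ± 3.66 CPM in 41-OX and 10.2 ± 0.899 CPM in WT (n = 4 each, log2 change 1.69, SE 0.28, adjusted p = 0.0211). In shoots it stood at 25.3 ± 0.986 CPM in 41-OX, 14.4 ± 5.10 CPM in WT and 11.3 ± 1.65 CPM in pxy (n = 4 each). The log2 changes in shoots were 0.60 (SE 0.13, adjusted p = 0.000782) in 41-OX and -0.56 (SE 0.14, adjusted p = 0.0339) in pxy. PXY (AT5G61480, chromosome 5, 24724337 to 24728244, 2 exons) was counted in every group including the mutant. In pxy shoots it stood at 35.5 ± 2.63 CPM against 6.72 ± 4.56 CPM in WT (n = 4 each, log2 change 2.01, SE 0.13, adjusted p = 1.87e-10). In 41-OX shoots it stood at 14.9 ± 1.18 CPM (n = 4, log2 change 0.75, SE 0.14, adjusted p = 0.000122). WT shoot replicate 2 held no PXY read, and the other 3 WT shoots averaged 8.96 ± 1.04 CPM. In roots PXY did not pass the test, at 16.2 ± 4.15 CPM in pxy, 16.5 ± 1.99 CPM in 41-OX and 21.1 ± 4.08 CPM in WT (n = 4 each, log2 changes -0.37 and -0.35, adjusted p = 0.437 and 0.930). Counts per gene do not show where reads fall, so whether pxy makes a full transcript could not be examined. The CLE41 call in roots was lost without any 1 of the 8 WT and 41-OX root libraries, with an adjusted p up to 0.10, and had an adjusted p of 1.39e-05 without the library labelled pxy root replicate 2. The CLE41 call in pxy shoots was lost without WT shoot replicate 3 or 4 or pxy shoot replicate 1, 3 or 4, with an adjusted p up to 0.290. The CLE41 call in 41-OX shoots was lost in the fit of all 24 libraries (adjusted p = 0.115).

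**Figure D2:**
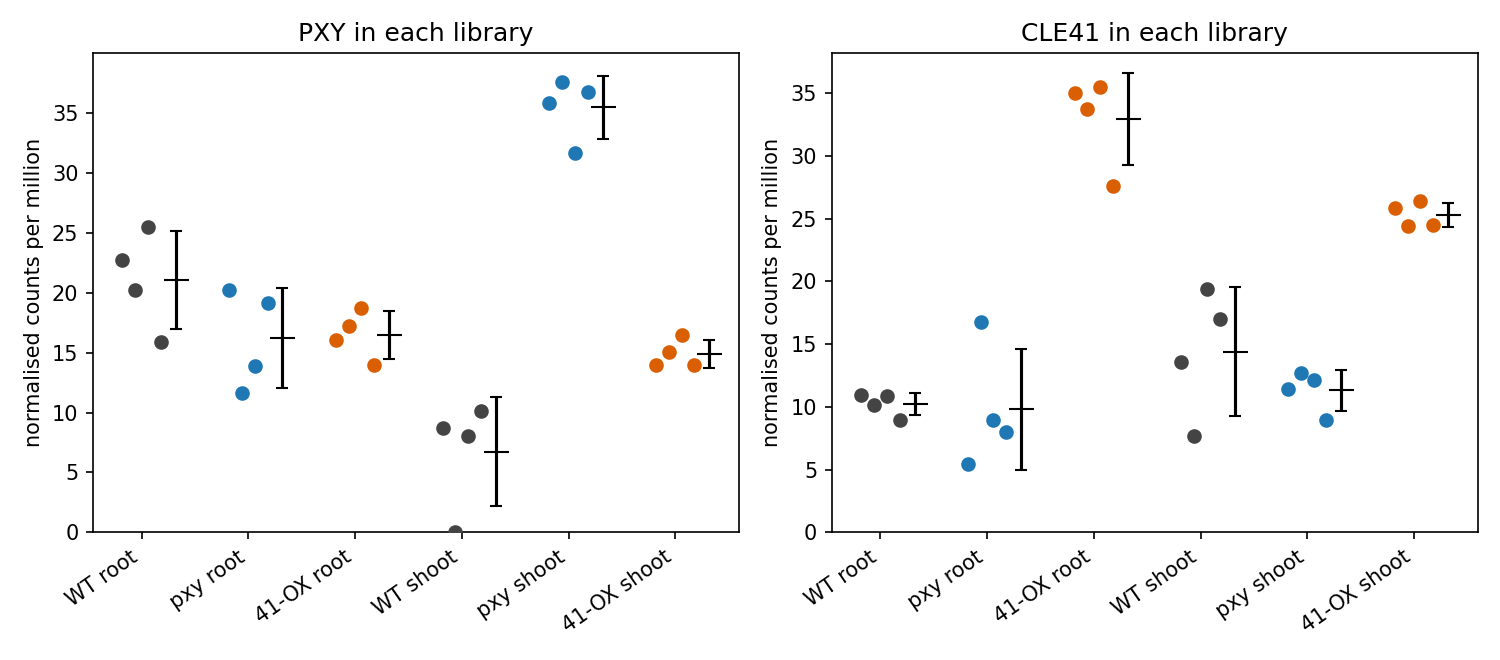
Normalised CPM of PXY (left) and CLE41 (right) in each library, with the mean and SD of the 4 libraries of each group beside the points. CLE41 averages 33.0 in 41-OX roots and 10.2 in WT roots, and PXY averages 35.5 in pxy shoots and 6.72 in WT shoots.

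The comparison of pxy with WT asks which genes differ in a mutant of the receptor gene. In pxy shoots, some jasmonate, wounding and ethylene response genes were lower than in WT shoots. In the jasmonate and wounding list 6 of 20 measured members fell and 14 did not pass, and 9 fell and 4 rose adjusted over the list alone (median log2 change -0.24, camera adjusted p = 0.00430). Its adjusted p = 0.466 with an estimated correlation. Without WT shoot replicate 3 the median difference in log2 CPM stayed negative (-0.121, adjusted p = 0.00717), but the list's mean deviation per library was higher in pxy (0.133) than in the other 3 WT shoots (0.0819). That order turned on WT shoot replicate 2 (-0.490), since WT shoot replicates 1 and 4 (0.383 and 0.353) stood above every pxy shoot (0.0721 to 0.218). WRKY33 (AT2G38470), a regulator of camalexin and pathogen response, fell from 81.0 ± 5.21 to 35.9 ± 3.6 CPM (n = 4 each, log2 change -1.20, SE 0.09, adjusted p = 8.07e-09). CML38, a calmodulin-like protein gene induced by wounding, fell with a log2 change of -1.42 (SE 0.17), and WRKY40 with -1.2 (SE 0.16). The zinc finger gene ZAT10 fell with -1.80 (SE 0.34), and had an adjusted p of 0.0594 without pxy shoot replicate 3. In the ethylene and ERF list 6 of 19 fell and 13 did not pass, and 8 fell and 1 rose adjusted over the list alone (median -0.19, camera adjusted p = 0.0176). Its adjusted p = 0.466 with an estimated correlation, and its camera adjusted p was 0.0686 without WT shoot replicate 4 and 0.0893 without pxy shoot replicate 1. The ethylene response factor genes ERF5 (-1.17, SE 0.16) and ERF6 (-0.78, SE 0.12) fell.

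Other genes that fell in pxy shoots were the cold regulator CBF1 (log2 change -1.36, SE 0.18), the indole glucosinolate enzyme gene CYP81F2 (-1.45, SE 0.20) and the salicylate regulator WRKY70 (-1.74, SE 0.32). WOX4 (AT1G46480), a homeobox gene that acts downstream of PXY in cambium division, fell from 7.90 ± 0.651 to 5.07 ± 0.891 CPM (n = 4 each, log2 change -0.67, SE 0.18, adjusted p = 0.0485). The WOX4 call was lost without any 1 of the 4 WT shoots or pxy shoot replicate 2, 3 or 4, with an adjusted p up to 0.260. PLT5 (AT5G57390), a transcription factor gene of the vascular proliferation list, fell with -1.40 (SE 0.30), and lost its call without WT shoot replicate 3 or pxy shoot replicate 4, with an adjusted p up to 0.175. In that list 2 of 22 fell, and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.210). Genes that rose included the expansin gene EXPA16 (0.96, SE 0.16) and the brassinosteroid synthesis gene BR6OX2 (0.59, SE 0.11). The pseudogene AT5G35935 on chromosome 5 rose from 0.503 ± 0.356 to 18.7 ± 1.26 CPM (n = 4 each, log2 change 4.76, SE 0.23, adjusted p = 6.91e-13).

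In the test of pxy against WT shoots, 350 of 19933 genes changed, of which 86 rose and 264 fell. The photosynthetic tissue list was called lower although no member passed over all genes or adjusted over the list alone (median -0.58, camera adjusted p = 0.000431, and adjusted p = 0.832 with an estimated correlation). Without WT shoot replicate 2, where the list took 6.19% of counts against 2.36% to 2.52% in the other WT shoots, the list's median difference in log2 CPM turned positive (0.0176, adjusted p = 0.760). The stomatal lineage list was called higher, again with no member passing over all genes or adjusted over the list alone (median 0.000258, camera adjusted p = 0.0339, and adjusted p = 0.847 with an estimated correlation). That call was lost without WT shoot replicate 2 (adjusted p = 0.505), WT shoot replicate 1 (0.0676), pxy shoot replicate 1 (0.127) or pxy shoot replicate 3 (0.0511). The count of changed genes was 120 without WT shoot replicate 3, 186 without WT shoot replicate 1, 172 without pxy shoot replicate 3 and 211 without pxy shoot replicate 4. It was 94 by DESeq2 and 11 when all 24 libraries were fitted together. Of the 19 called genes named for this contrast, 13 lost their call in the fit of all 24 libraries. Among them were CML38, WRKY40, ERF6, CBF1, CYP81F2, EXPA16 and BR6OX2. By DESeq2 5 of the 19 lost it, with only the 8 libraries compared 4, among them WRKY70, and with the replicate block 2.

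The comparison of 41-OX with WT asks which genes differ in a line that expresses the ligand gene constitutively. In 41-OX shoots, many genes of root cell types were higher than in WT shoots. In the root epidermis and uptake list 9 of 11 measured members rose and 2 did not pass, and 9 rose adjusted over the list alone (median log2 change 1.70, camera adjusted p = 1.44e-05). Its adjusted p = 0.184 with an estimated correlation. The root hair expansin gene EXPA7 (AT1G12560) rose from 0.347 ± 0.329 to 10.6 ± 0.828 CPM (n = 4 each, log2 change 4.37, SE 0.30, adjusted p = 1.33e-10), and EXPA18 (AT1G62980) from 0.660 ± 0.460 to 16.9 ± 3.5 CPM (n = 4 each, 4.28, SE 0.29). The root hair genes RHS18 (4.21, SE 0.38), MRH6 (4.24, SE 0.30) and RHD2, an NADPH oxidase gene (2.79, SE 0.25), rose, as did the aquaporin gene TIP2;3 (1.91, SE 0.16). In the endodermis and suberin list 10 of 11 rose and 1 did not pass, and 11 rose adjusted over the list alone (median 1.19, camera adjusted p = 0.00383). Its adjusted p = 0.466 with an estimated correlation. The Casparian strip genes PER64 (1.76, SE 0.22) and CASP1 (1.57, SE 0.21) and the suberin gene GPAT5 (1.18, SE 0.21) rose. Root-specific genes as a whole stood at 5.44% to 6.78% of the root mean in these 4 libraries.

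Some genes of vascular proliferation and cell division were also higher in 41-OX shoots. In the vascular proliferation list 10 of 22 members rose, 1 fell and 11 did not pass, and 11 rose and 1 fell adjusted over the list alone (median log2 change 0.25, camera adjusted p = 0.00430). Its adjusted p = 0.466 with an estimated correlation. The rises were 1.31 (SE 0.22) for PLT5, 0.74 (SE 0.14) for REV, 0.72 (SE 0.14) for the auxin response factor gene MP and 0.53 (SE 0.08) for PHB. REV and PHB encode class III homeodomain-leucine zipper factors that pattern vascular tissue. In the cell cycle list 11 of 27 members rose, 1 fell and 15 did not pass, and 13 rose and 1 fell adjusted over the list alone (median 0.33, camera adjusted p = 0.0109). Its adjusted p = 0.806 with an estimated correlation and 0.0783 by fry. The replication licensing gene CDT1A (0.74, SE 0.19), the kinase gene CDKB2;1 (0.60, SE 0.13) and the cyclin gene CYCB1;2 (0.57, SE 0.14) rose. Root RNA at 3.73%, the median excess of root-specific genes in these shoots, would alone give part of these rises. It would give medians of 0.11 for the cell cycle list and 0.03 for the vascular proliferation list. For single genes it would give 0.30 for CDT1A, 0.18 for CYCB1;2, 0.10 for CDKB2;1, 0.16 for REV, 0.08 for MP, 0.03 for PHB and 0.02 for PLT5. Whether the samples held such RNA is left open.

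In the TDIF-PXY pathway list 4 of 21 members rose in 41-OX shoots, and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.271). These were PXY, CLE41, HB8 (log2 change 0.55, SE 0.11) and TMO6 (0.35, SE 0.10), and TMO6 had an adjusted p of 0.0678 without WT shoot replicate 1. In the xylem and secondary wall list 6 of 28 rose and 1 fell, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.715). The vessel regulator gene VND6 rose (0.83, SE 0.20) and TED6 fell (-0.55, SE 0.11). In the phloem list 7 of 22 rose and 4 fell, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.973). OPS rose (0.98, SE 0.16), while SUC2 (-0.75, SE 0.09) and SULTR2;1 (-1.13, SE 0.11), transporter genes of phloem cells, fell.

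Many jasmonate genes and some ethylene genes were lower in 41-OX shoots. In the jasmonate and wounding list 16 of 20 members fell, 1 rose and 3 did not pass, with 16 and 1 adjusted over the list alone (median log2 change -1.0, camera adjusted p = 1.98e-05). Its adjusted p = 0.199 with an estimated correlation. WRKY33 fell from 81.0 ± 5.21 to 24.5 ± 2.80 CPM (n = 4 each, -1.74, SE 0.09, adjusted p = 4.93e-12). CML38 (-2.32, SE 0.18), WRKY40 (-1.81, SE 0.17) and the jasmonate synthesis gene AOS (-0.90, SE 0.10) fell too. In the ethylene and ERF list 10 of 19 fell, 2 rose and 7 did not pass, with 10 and 2 adjusted over the list alone (median -0.41, camera adjusted p = 0.00399). Its adjusted p = 0.466 with an estimated correlation. ERF5 (-1.53, SE 0.16) and ERF6 (-1.47, SE 0.12) fell, while ACO1, an enzyme gene of ethylene synthesis, rose (1.86, SE 0.21). In the salicylate defence list 2 of 8 rose and 4 fell, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.158), and WRKY70 (-2.23, SE 0.33) and EDS1 (-0.56, SE 0.10) were among those that fell. CBF1 (-2.56, SE 0.20), the receptor kinase gene CRK41 (-2.97, SE 0.28), AT1G53870 (-3.03, SE 0.22) and AT3G04640 (-2.51, SE 0.14) fell as well.

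Members of the hormone and clock lists went both ways in 41-OX shoots. In the cytokinin response list 3 of 15 rose and 6 fell, with 3 and 6 adjusted over the list alone (camera adjusted p = 0.645). The response regulator gene ARR3 (AT1G59940) rose from 0.608 ± 0.440 to 7.07 ± 0.763 CPM (n = 4 each, log2 change 3.09, SE 0.28, adjusted p = 7.91e-09), while ARR5 (-0.64, SE 0.13) and ARR9 (-0.60, SE 0.09) fell. In the auxin response list 5 of 20 rose and 7 fell, with 5 and 10 adjusted over the list alone (camera adjusted p = 0.281). GH3.2 (1.2, SE 0.16) and IAA20 (2.09, SE 0.45) rose and IAA3 (-0.58, SE 0.10) fell. In the circadian clock list 3 of 9 rose and 2 fell, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.795). PRR9 (-1.29, SE 0.15) and CCA1 (-0.92, SE 0.16) fell and LUX (0.40, SE 0.09) rose.

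Anthocyanin genes rose in 41-OX shoots, with 3 of 3 measured members over all genes and 3 adjusted over the list alone (median log2 change 1.16, camera adjusted p = 0.0244). The list's adjusted p = 0.466 with an estimated correlation, and its camera adjusted p was 0.0638 without WT shoot replicate 1. The members were TT19 (1.65, SE 0.39), LDOX (1.16, SE 0.29) and CHS (0.80, SE 0.15). The photosynthetic list was called lower, with 2 of 14 fallen and no member adjusted over the list alone (median -0.85, camera adjusted p = 0.00227, and adjusted p = 0.847 with an estimated correlation). Without WT shoot replicate 2 the list's median difference in log2 CPM went from -0.710 to -0.284 (adjusted p = 0.0228). SPCH, which starts the stomatal lineage, rose (1.42, SE 0.28), while the stomatal lineage list was not called in 41-OX shoots. The transporter gene UMAMIT35 rose too (4.42, SE 0.47). AT2G06590, a pseudogene on chromosome 2, had 320 counts in 41-OX shoots and none in WT shoots, at least 93.2-fold higher against a floor of 3 counts over the group.

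In the test of 41-OX against WT shoots, 5955 of 19933 genes changed, 2846 up and 3109 down. DESeq2 called 3295 (1687 up, 1608 down) and a fit of all 24 libraries 1231 (783 and 448). Among only the genes within 1.5-fold between organs, where fewer genes were tested by construction, 1067 were called (383 and 684). With DESeq2 size factors in edgeR 3303 rose and 2671 fell, and with a 2-fold threshold 987 and 479, so which direction held more genes depended on the method. Of the 56 called genes named for this contrast, 23 lost their call in the fit of all 24 libraries. Among them were CLE41, CHS, TT19, LDOX, CDT1A, CDKB2;1, CYCB1;2, REV, GPAT5, AOS, CBF1, SUC2, SULTR2;1, CCA1 and SPCH. By DESeq2 3 of the 56 lost it, TMO6, LDOX and VND6.

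**Figure D3:**
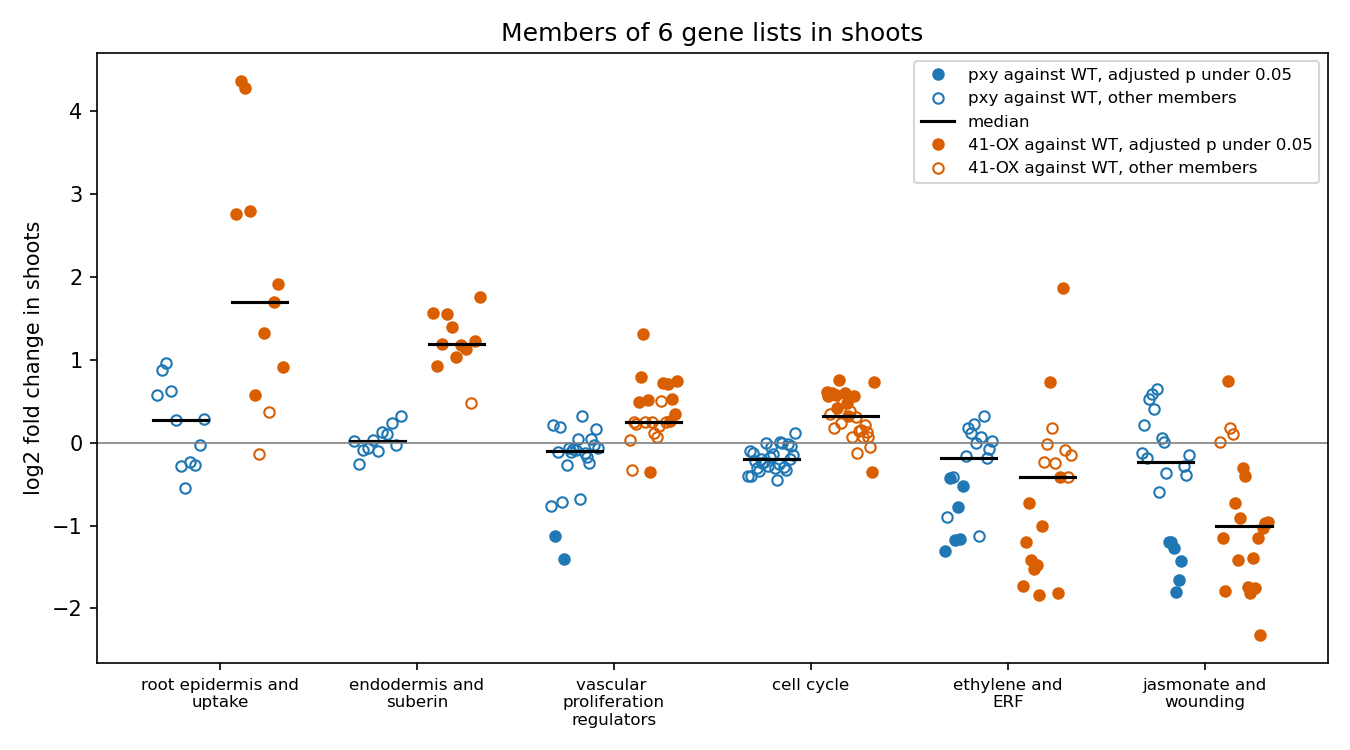
Log2 fold change against WT in shoots (vertical) of the measured members of 6 gene lists, blue for pxy and orange for 41-OX, filled where the adjusted p was under 0.05, with the median of each list as a black line. The root epidermis list has a median of 1.70 in 41-OX, and the jasmonate list -1.0 in 41-OX and -0.24 in pxy.

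The comparison of 41-OX with pxy sets that line against a mutant of the receptor gene. In shoots, many vascular proliferation, cell cycle and root epidermis genes were higher in 41-OX than in pxy. In the vascular proliferation list 15 of 22 members were higher and 1 lower, with 16 and 1 adjusted over the list alone (median log2 difference 0.46, camera adjusted p = 9.02e-07, and adjusted p = 0.130 with an estimated correlation). In the cell cycle list 19 of 27 were higher, and 19 adjusted over the list alone (median 0.55, camera adjusted p = 2.11e-05, and adjusted p = 0.380 with an estimated correlation). The root epidermis list, with 9 of 11 higher and 10 adjusted over the list alone, kept its call (median 1.94, camera adjusted p = 1.07e-09, and adjusted p = 0.0182 with an estimated correlation). In the jasmonate list 12 of 20 were lower, and 12 adjusted over the list alone (median -0.57, camera adjusted p = 0.000190, and adjusted p = 0.130 with an estimated correlation). These list tests were adjusted over 38 tests and chosen after seeing the data.

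Single genes higher in 41-OX than in pxy shoots were MRD1 (log2 difference 4.81, SE 0.43), RAP2.11, a transcription factor gene of the low-potassium response (3.66, SE 0.31), and SESA5, a seed storage albumin gene (3.54, SE 0.49). CORI3 (-3.17, SE 0.25), a gene induced by coronatine, and the floral regulator gene BFT (-3.23, SE 0.50) were lower. AT5G35935 stood at 0.196 ± 0.141 CPM in 41-OX and 18.7 ± 1.26 CPM in pxy shoots (n = 4 each, -6.39, SE 0.26). The test called 5440 of 19933 genes, 2729 higher and 2711 lower in 41-OX. DESeq2 called 2744 (1645 higher, 1099 lower) and a fit of all 24 libraries 793 (614 and 179). Among only the genes within 1.5-fold between organs, again with fewer genes tested, 827 were called (248 and 579). With DESeq2 size factors in edgeR 3208 were higher and 2144 lower, and with a 2-fold threshold 897 and 224, so here too the balance depended on the method.

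Genes that went opposite ways in pxy and in 41-OX numbered 13 in shoots. PLT5 fell in pxy (-1.40) and rose in 41-OX (1.31), and CLE41 itself went -0.56 and 0.60. The aquaporin gene PIP2;8 fell in pxy (-0.81, SE 0.15) and rose in 41-OX (0.99, SE 0.14), and so did the ABC transporter gene ABCC13 (-0.69, SE 0.14 and 0.73, SE 0.13). The jasmonate synthesis gene AOC1 rose in pxy (0.79, SE 0.14) and fell in 41-OX (-0.84, SE 0.16). In pxy, the calls of PIP2;8 and ABCC13 were lost without WT shoot replicate 3 (adjusted p = 0.0781 and 0.0838). Another 286 genes changed the same way in both genotypes, 57 up and 229 down, among them WRKY33, CML38, ERF5 and CBF1. Both contrasts share the WT libraries. Among 48 simulated sets of unchanged groups edgeR found no gene in either class, but with nothing changed few calls were possible. Over all tested genes the log2 changes of the contrasts correlated at r = 0.497, against a simulated median of 0.577. Their covariance was 0.0795, against a simulated median of 0.0181. Independent lists of the same sizes would give 12.3 genes up in both, 41.2 down in both and 51.1 opposite. Against 2 separate WT libraries each, the counts were 1 to 14 opposite and 8 to 232 in the same direction. The opposite count was 4 without WT shoot replicate 3, 5 without WT shoot replicate 1, and 7 without WT shoot replicate 4 or pxy shoot replicate 3 or 4. It was 2 by DESeq2, and with all 24 libraries in 1 edgeR fit no gene went opposite ways.

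In pxy roots few genes were called against WT by edgeR. As labelled, 1 of 20161 genes was called by edgeR, the retroelement pseudogene SADHU3-2 (AT3G42658), which fell from 6.47 ± 0.353 to 1.53 ± 0.441 CPM (n = 4 each, log2 change -2.08, SE 0.22, adjusted p = 0.0197). With the library labelled pxy root replicate 2 left out, 8 of 20300 genes changed, 2 up and 6 down. AT5G35935 then rose from 1.54 ± 0.266 CPM (n = 4) to 39.2 ± 6.33 CPM (n = 3, log2 change 4.65, SE 0.26, adjusted p = 1.72e-06). AT5G35940, 682 bases from it, fell from 168 ± 11.5 CPM (n = 4) to 90.2 ± 13.0 CPM (n = 3, -0.91, SE 0.10, adjusted p = 0.00337). The zinc transporter gene ZIP3 rose (0.58, SE 0.09, adjusted p = 0.0303), and lost its call without any 1 of the 4 WT roots, pxy root replicate 1 or 4 or 41-OX root replicate 1, 2 or 3, with an adjusted p up to 0.157. AT3G29120 fell (-1.81, SE 0.22), and lost its call without pxy root replicate 1 or 4 (adjusted p up to 0.0570), as did AT5G22860 (-1.21, SE 0.15) without pxy root replicate 4 (adjusted p = 0.0543). AT2G06845 fell from 6.91 ± 0.981 CPM (n = 4) to 0.194 ± 0.336 CPM (n = 3, adjusted p = 0.0124), and lost its call without WT root replicate 3 or 4 or pxy root replicate 1 or 4 (adjusted p up to 0.0939).

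As labelled, 2375 genes had an unadjusted p under 0.05 in pxy roots, and DESeq2 called 20. The SADHU3-2 call was lost without any 1 of the 4 WT roots, pxy root replicate 1, 3 or 4 or 41-OX root replicate 4, with an adjusted p up to 0.166 and log2 changes of -2.1 to -1.98. With the library labelled pxy root replicate 2 left out, SADHU3-2 was among the 8 genes (-2.29, SE 0.21, adjusted p = 0.000414), and kept its call in each of the 11 fits without 1 further library, while DESeq2 gave it no adjusted p. DESeq2 then called 96 genes, 93 up and 3 down, against 2 up and 6 down by edgeR. Of the 7 called genes named for this fit, 5 were not called by DESeq2. These were SADHU3-2, AT5G35935, also without an adjusted p, AT2G06845, AT3G29120 and AT5G22860. With the replicate block 4 of the 7 lost their call, ZIP3, AT2G06845, AT3G29120 and AT5G22860. The count of 8 was then 3 without pxy root replicate 4 and 5 without WT root replicate 3 or 4 or pxy root replicate 1.

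As labelled, 5 lists were called lower in pxy roots by camera, with no member passing over all genes or adjusted over the list alone. These were cell cycle (median log2 change -0.28, adjusted p = 2.73e-05), xylem and secondary wall (-0.19, 0.00533), vascular proliferation (-0.15, 0.00533), root epidermis (-0.29, 0.00533) and heat and handling stress (-0.37, 0.0244). In the same order, adjusted p = 0.832, 0.847, 0.466, 0.847 and 0.466 with an estimated correlation. The vascular proliferation call was lost without pxy root replicate 1 (adjusted p = 0.0862), and the heat call without WT root replicate 3 (0.0768), pxy root replicate 3 (0.131) or pxy root replicate 4 (0.117). With the library labelled pxy root replicate 2 left out, cell cycle was not called (adjusted p = 0.187), and the medians of the xylem and root epidermis lists were positive (0.04 and 0.06). Vascular proliferation (-0.16, adjusted p = 0.00311, and adjusted p = 0.398 with an estimated correlation) and heat and handling stress (-0.46, 0.0237, and adjusted p = 0.430 with an estimated correlation) were called then as well, with no member passing over all genes or adjusted over the list alone. Lists called lower only then were TDIF-PXY pathway (median -0.19, adjusted p = 0.0331), phloem (-0.24, 0.0446), anthocyanin with 1 measured member (-0.87, 0.0331) and photosynthetic tissue (-1.10, 0.0237). Cytokinin response (0.16, 0.0348) and endodermis (0.13, 0.00798) were called higher. With an estimated correlation, adjusted p = 0.398, 0.683, 0.398, 0.790, 0.398 and 0.430 for these 6. None of their members passed over all genes. Adjusted over the list alone, 1 member fell in TDIF-PXY pathway and 1 in anthocyanin, and 3 rose in cytokinin response and 4 in endodermis.

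In 41-OX roots, CLE41 rose, and LSU1, MAF4, MAF5, CKX4 and ARR16 were among the genes that fell. LSU1 (AT3G49580), a gene of sulfur deficiency, fell from 12.1 ± 1.87 to 1.38 ± 0.732 CPM (n = 4 each, log2 change -3.11, SE 0.40, adjusted p = 0.00597). The transcription factor gene MYB69 (-3.07, SE 0.33) and the glycosyltransferase gene UGT71B8 (-3.04, SE 0.29) fell. The flowering repressor genes MAF4 (-2.41, SE 0.30) and MAF5 (-2.37, SE 0.22), 1301 bases apart on chromosome 5, and the transporter gene ABCA8 (-2.39, SE 0.20) fell. The malate channel gene ALMT1 (-2.31, SE 0.40) and the cytokinin genes CKX4 (-1.50, SE 0.25) and ARR16 (-1.40, SE 0.27) fell, and lost their calls without any 1 of the 8 WT and 41-OX roots (adjusted p up to 0.139, 0.116 and 0.149). In the cytokinin response list 2 of 19 fell, and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.569). AT5G48430 rose (2.52, SE 0.36), and had an adjusted p of 0.0516 without WT root replicate 1. As labelled, 137 of 20161 genes changed, 14 up and 123 down. The jasmonate list was called lower, with 1 of 18 fallen and 3 adjusted over the list alone (median -0.20, camera adjusted p = 0.00430). Its adjusted p = 0.426 with an estimated correlation.

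The library labelled pxy root replicate 2 belongs to neither of these groups but enters the shared spread. With it left out, 1332 of 20300 genes changed between 41-OX and WT roots, 389 up and 943 down, and all 137 genes were among them with the same direction. Of the endodermis list 3 of 11 fell and 1 rose, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.293). The suberin genes FAR4 (log2 change -1.46, SE 0.12), GPAT5 (-0.85, SE 0.14) and ASFT (-0.58, SE 0.10) fell. In the jasmonate list 4 of 18 fell, and 6 adjusted over the list alone (camera adjusted p = 0.0237, and adjusted p = 0.398 with an estimated correlation). JAZ1 (-0.55, SE 0.10), ZAT10 (-0.81, SE 0.14) and the storage protein genes VSP1 (-1.29, SE 0.09) and VSP2 (-1.09, SE 0.22) fell. In the root epidermis list 5 of 12 rose and 1 fell, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.00998, and adjusted p = 0.398 with an estimated correlation). The phosphate transporter gene PHT1;1 (0.66, SE 0.08) and TIP2;3 (0.44, SE 0.07) rose. In the auxin list 4 of 22 rose and 1 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.00998, and adjusted p = 0.398 with an estimated correlation), and GH3.2 rose (1.03, SE 0.13). The cell cycle list was called higher with no member passing over all genes or adjusted over the list alone (median 0.10, camera adjusted p = 0.0237, and adjusted p = 0.771 with an estimated correlation). NAS4, a nicotianamine synthase gene (2.74, SE 0.38), and the systemic resistance genes FMO1 (1.53, SE 0.27) and ALD1 (1.25, SE 0.27) rose. WOX4 fell (-1.07, SE 0.30, adjusted p = 0.0482), and lost its call without any 1 of the 8 WT and 41-OX roots or pxy root replicate 4 (adjusted p up to 0.148).

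As labelled, the count for 41-OX roots was 39 to 66 without any 1 of the 4 WT and 4 41-OX root libraries. It was 2382 when those 8 libraries were fitted alone, and 433 by DESeq2. The count of 1332 was 859 without WT root replicate 3, 883 without WT root replicate 4, 871 without 41-OX root replicate 2 and 2470 without pxy root replicate 3. It was 1277 without 41-OX root replicate 4, which held shoot-specific genes at 11.4% of the shoot mean.

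Between 41-OX and pxy roots, LSU1 (log2 difference -3.55, SE 0.41), MYB69 (-3.07, SE 0.33) and MAF4 (-2.57, SE 0.30) were lower in 41-OX, as they were against WT. AT5G48430 (2.85, SE 0.37) and AT3G46400 (2.59, SE 0.34) were higher. As labelled, 230 of 20161 genes were called, 33 higher and 197 lower in 41-OX. With the library labelled pxy root replicate 2 left out there were 1983 of 20300, 630 higher and 1353 lower, including all 230 with the same direction. MRD1 was then higher (3.59, SE 0.56), and ALMT1 (-2.78, SE 0.19) and AT5G35935 (-5.62, SE 0.28) were lower. As labelled, the count was 80 to 105 without any 1 of the 41-OX root libraries and 141 without pxy root replicate 1. It was 33 when the 8 libraries were fitted alone and 999 by DESeq2. The count of 1983 was 1247 without 41-OX root replicate 2.

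In roots as labelled, edgeR and DESeq2 found no gene that went opposite ways in pxy and 41-OX, with 2375 and 1456 genes at an unadjusted p under 0.05 in the edgeR tests. With the library labelled pxy root replicate 2 left out, AT5G35940 fell in pxy (-0.91) and rose in 41-OX (0.44, SE 0.09, adjusted p = 0.00985). It was the 1 such gene by edgeR, against 16 by DESeq2. There were 2 when pxy root replicate 1 or 41-OX root replicate 3 was left out too.

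Whether an effect differed between organs was tested as root minus shoot. For pxy, PXY was the 1 gene called of 21245 (-2.43, SE 0.28, adjusted p = 0.000585). Its adjusted p was 0.153 (difference -2.5), and no gene was called, with a block joining root and shoot by genotype and number, and it was 2.57e-10 to 0.153 over its alternatives. With the library labelled pxy root replicate 2 left out, 5 of 21406 genes differed, PXY, WRKY33 (1.12, SE 0.16), AT3G04640 (1.40, SE 0.24), AT4G28290 (1.03, SE 0.19) and AT3G29120 (-1.47, SE 0.26). The count as labelled was 4 without WT shoot replicate 4 and 5 without pxy root replicate 4.

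For 41-OX, 402 of 21245 genes differed between organs, 65 with a more positive and 337 with a more negative log2 change in roots. AT2G32210 went from 8.67 ± 2.18 CPM in WT to 1.19 ± 0.378 CPM in 41-OX shoots and from 1.62 ± 0.454 to 2.70 ± 0.593 CPM in roots (n = 4 each, root minus shoot 3.65, SE 0.72, adjusted p = 0.0126). AT1G13540 went from 2.86 ± 1.98 to 1.69 ± 0.465 CPM in shoots and from 2.58 ± 0.134 to 4.59 ± 0.693 CPM in roots (n = 4 each, 2.00, SE 0.41). AT1G74830 had no count in WT shoots, 1.48 ± 0.236 CPM in 41-OX shoots, and 14.7 ± 3.41 and 13.1 ± 0.517 CPM in WT and 41-OX roots (n = 4 each). AT5G43175 had no count in WT shoots, 1.54 ± 0.252 CPM in 41-OX shoots, and 3.08 ± 0.894 and 2.1 ± 0.351 CPM in WT and 41-OX roots (n = 4 each). Without WT shoot replicate 3 the count was 89, and AT2G32210, AT1G13540, AT1G74830 and AT5G43175 had adjusted p of 0.0504, 0.0593, 0.0655 and 0.0535. All 4 genes also lost their call with the block joining root and shoot by genotype and number. With a block by replicate number within each organ 3 of the 4 lost it, and fewer genes were called with either block. The count was 161 to 266 without any 1 of the 4 WT roots, WT shoot replicate 1 or 4, 41-OX root replicate 1, 2 or 4, or any 1 of the 4 41-OX shoots. It was 3435 of 21406 with the library labelled pxy root replicate 2 left out, and the 402 genes were among them with the same direction.

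As labelled, 18 of the 76 list tests against WT were called. With an estimated correlation camera called none, and fry called 8, of which 6 were among the 18. Lists called by camera in no contrast against WT as labelled had these smallest camera adjusted p over those contrasts: TDIF-PXY pathway 0.271, lignin biosynthesis 0.138, phloem 0.0869, auxin response 0.138, cytokinin response 0.150, brassinosteroid biosynthesis 0.408, salicylate defence 0.158 and circadian clock 0.429. The contrast of 41-OX with pxy is not among these. Median, mean and test differed in sign in 13 of the 76, none of them called. For the endodermis list in 41-OX roots the median was 0.01 and the mean -0.24.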

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

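The tests of the near-shoot library, of root tissue and of the jasmonate genes, and the counts over other splits, were chosen after the results were seen; the test of each sample's distance from its group and the root-minus-shoot tests were planned.

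A value was marked where 1 of 4 libraries lay far from the other 3. This held for 38 of 296 groups of 4, where chance gives about 1 in 20, or 14.8. It held 8 times for the library labelled pxy root replicate 2, 7 times for WT shoot replicate 2 and 23 times elsewhere.

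The library labelled pxy root replicate 2 held shoot-specific genes at 93.7% of the shoot mean and root-specific genes at 5.24% of the root mean, against 0.392% to 0.723% and 98.5% to 101% in the other pxy roots. An exchange with another library of the series is argued against, since no library labelled shoot held root-specific genes above 6.78% of the root mean. Root RNA as a large part of the library is argued against as well, at 5.24%. A small share of root RNA in shoot RNA is not, since WT and pxy shoots stood at 0.702% to 1.43%. Of the loci marking pxy in both organs, in CPM without TMM scaling, 2 of 2 stood nearer the WT level (AT5G35935 at 1.03 against 17 to 20.2 in pxy shoots), and of those marking 41-OX 2 of 2 (AT2G06590 at 0.644 against 8.82 to 12.4), which argues against shoot RNA of either line alone; AT2G06845 is in both sets, so the loci are 3. PXY goes with this, with 70 counts in a total of 7765685, against 251 to 324 counts in pxy shoots with totals of 7291630 to 8638785. In TMM-normalised CPM it stood at 11.6 against 31.7 to 37.6, scaled apart in the root and the shoot fit. In 41-OX shoots, with totals of 7033091 to 9025246, PXY had 113 to 148 counts. CLE41 had 101 counts in this library and 191 to 240 in 41-OX shoots. WT shoots other than replicate 2, with totals of 7868951 to 11052295, held 76 to 92 counts of PXY and 119 to 221 of CLE41. Both genes thus go against 41-OX shoot RNA alone. AT2G06590, however, had 5 counts here and 0 in the 8 WT libraries. The shoot-specific level of 93.7% could come from shoot RNA under this label, but its line is left open, since the root-specific level was near that of 41-OX shoots (5.44% to 6.78%) and above that of WT and pxy shoots (0.702% to 1.43%); no biological explanation was tested.

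Root-specific genes were higher in 41-OX shoots, at 5.44% to 6.78% of the root mean. Shoot-specific genes stood at 81.8% to 88.0% of the shoot mean in these libraries. They stood at 93.8% to 103% in the WT and pxy shoots on which they were chosen, and at 90.5% in WT shoot replicate 2. Whole root tissue in the samples would raise root-specific genes by 1 common share. The excess per root level ran from 1.67% to 17.5% (5th to 95th percentile), a ratio of 10.5. Single 41-OX root libraries gave 1.28 to 1.38, each set against a mean that includes it. This argues against whole root tissue as the only source of the excess, but not against a share of it. A root share set at the median excess, 3.73%, would alone give median log2 changes of 1.22 for the root epidermis list and 0.53 for the endodermis list. Both are below the medians found. For the genes that fell, 2728 did so by more than the highest root level allows (-0.10 on the log2 scale), which argues against whole root tissue at that level as their cause. That level is a median over root-specific genes, so a larger share of a part of the root is not covered. The 479 genes that fell at least 2-fold did so by more than a share of 21.4% would give. That was the highest excess among the 73 root-specific genes with at least 50 CPM in 41-OX roots. A part of the root or an effect of CLE41 on shoots may underlie the pattern, and the 10.5-fold range does not decide between them.

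Some jasmonate, wounding and ethylene genes were lower in pxy and 41-OX shoots. The mean deviation of the jasmonate list (log2) was 0.383, -0.490, 0.731 and 0.353 in WT shoot replicates 1 to 4, 0.0721 to 0.218 in pxy and -0.473 to -0.275 in 41-OX. For pxy, a high level in WT shoot replicate 3 alone is left open: the list's adjusted p without it was 0.00717, but the mean of the other 3 WT shoots (0.0819) was below that of pxy (0.133), an order that turns on WT shoot replicate 2 with its 167131 counts, and without both only 2 WT shoots remain. A high level in the WT shoots alone is argued against for 41-OX, where 12 of 20 members were lower than in pxy and the means per library did not overlap (exact permutation test, two-sided, p = 0.0286, the smallest it can give with 4 against 4; camera adjusted p = 0.000190, and 0.130 with an estimated correlation). For pxy such a level cannot be told apart from an effect of the mutant, since each comparison rests on the same WT shoots and the list's adjusted p = 0.466 with an estimated correlation.

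In the library labelled pxy root replicate 2 the photosynthetic list took 2.50% of its counts (0.0283% to 0.0462% in the other pxy roots) and the root list 0.103% (0.331% to 0.344%), and ZIP3 stood at 9.44 CPM, AT2G06845 at 8.28, AT3G29120 at 14.6 and AT5G22860 at 29.2. WT shoot replicate 2, the library of 167131 counts, stood apart in the share of the photosynthetic list (6.19%), the share of the top 10 genes (6.52%) and the level of shoot-specific genes (90.5%), and in BR6OX2 (22.9 CPM), ABCC13 (0 CPM), AOS (30.6 CPM) and EDS1 (61.2 CPM). In 41-OX root replicate 4 the photosynthetic list took 0.454%, the top 10 genes 0.935%, shoot-specific genes stood at 11.4% and CKX4 at 3.5 CPM. In 41-OX shoot replicate 2 the top 10 genes took 1.99%, root-specific genes stood at 6.78%, CRK41 at 1.32 CPM, TT19 at 2.75 CPM and AT5G35935 at 0.407 CPM. WT shoot replicate 3 held ZAT10 at 23.4, CML38 at 63.0 and AT2G32210 at 11.9 CPM. The rest were reads with no feature in pxy root replicate 4 (2.1%), MAF4 (8.80 CPM) and AT1G74830 (19.8 CPM) in WT root replicate 2, GPAT5 (52.9 CPM) in WT root replicate 3, AT2G32210 (0.945 CPM) in WT root replicate 4, ALD1 (20.2 CPM) in 41-OX root replicate 1, CML38 (14.0 CPM) and AOC1 (15.4 CPM) in pxy shoot replicate 1, MRH6 (11.8 CPM) and VND6 (5.26 CPM) in 41-OX shoot replicate 4, and ERF6 (19.4 CPM) in 41-OX shoot replicate 3.

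Effects that differed between organs by the test of the difference were 1 gene for pxy, PXY at -2.43, and 402 genes for 41-OX, among them AT2G32210 (3.65) and AT1G13540 (2.00). The fitted values of AT5G43175 (-7.45) and AT1G74830 (-7.03) rest on 0 counts in WT shoots and are no bounds.

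Chance as a cause of the counts was examined with other splits of the same samples. It is argued against where fewer than 1 in 20 splits gave as many, unless the splits could not answer the question. This says nothing on how far a count depends on the tool or on single libraries. For single comparisons only the real one of 35 splits gave as many genes (1 of 35). That is the smallest share these splits can give, and shares were not adjusted over the counts examined. Chance is argued against for 137 genes in 41-OX roots (highest other 0) and 230 for 41-OX against pxy roots (0). The same holds for 350 in pxy shoots (66), 5955 in 41-OX shoots (1479) and 5440 for 41-OX against pxy shoots (0). Without the library labelled pxy root replicate 2 it holds for 8 (0), 1332 (0) and 1983 (6). For pxy roots as labelled, 1 gene stood against 0 in the other splits, which is too few to argue against chance. The 1 gene of pxy roots, SADHU3-2, lost its call in 8 of the 9 left-out fits with little change in its fold (-2.1 to -1.98 against -2.08, SE 0.22), and kept it without the library labelled pxy root replicate 2 (-2.29, SE 0.21). Chance is argued against for the 8 lists called in 41-OX shoots (1 of 35, highest other 7), but each lost its call with an estimated correlation (smallest adjusted p = 0.184). It cannot be excluded for lists called in pxy roots (5, with 32 of 35 splits as large and a highest other of 10), 41-OX roots (1, 31 of 35, 6) and pxy shoots (4, 7 of 35, 7).

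For genes changed in both genotypes the splits mixed all 3 genotypes, which removes the effects of both lines. They do not show how many genes lists of the observed sizes would share by chance, so chance is not called excluded here. The 13 opposite in shoots came in 1 of 100 splits (highest other 0). Independent lists of these sizes would give 51.1, more than the 13, and DESeq2 gave 2. The 286 of the same direction came in 2 of 100, and another split gave 348. The 1 opposite gene in roots without the library labelled pxy root replicate 2 came in 1 of 100 (highest other 0). The count of 0 as labelled was reached by 100 of 100. For the root-minus-shoot counts the splits mixed genotypes within both organs. They bear on no effect in either organ, not on an equal effect in both, so chance is not called excluded here. Counts as large as the 402 of 41-OX came in 1 of 50 splits (highest other 156). The 1 of pxy came in 2 of 50 (highest other 1). This gene is PXY, called in each of the 17 left-out fits (adjusted p up to 0.00627) though not with the block joining root and shoot (0.153). Without the library labelled pxy root replicate 2 it was 1 of 49 for the 5 of pxy (highest other 4). For the 3435 of 41-OX it was 2 of 50 (highest other 3666). The splits with 1, 4 and 3666 kept the shoot genotypes whole with 4, 2 and 4 root libraries out of place, so the shoot effect alone could give such counts, and these 3 counts alone show no effect in roots.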

How the results depend on the processing

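Chosen after seeing the data were the results without the library labelled pxy root replicate 2 with all their alternatives, fits without 1 library of a group not compared, fits without several libraries together, and genes within 1.5-fold between organs; the others were planned, among them leaving out each library of the groups compared in turn, and so that library where pxy is compared. One technical run per sample could not be tried, since the file does not hold runs apart. Causes were not tested, except that fewer genes or samples enter some fits by construction.

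The order of results is pxy, 41-OX and 41-OX against pxy in roots (1, 137 and 230 genes), then in shoots (350, 5955 and 5440). DESeq2 gave 20, 433 and 999, then 94, 3295 and 2744; all 24 libraries in 1 fit 2, 322 and 1103, then 11, 1231 and 793; genes within 1.5-fold between organs 0, 61 and 132, then 77, 1067 and 827. For roots the replicate block gave 0, 39 and 74, and the 8 libraries of the groups compared 0, 2382 and 33; the 2-fold threshold gave 57, 1466 and 1121 for shoots. No pairing by replicate number was seen (own number best in 6 of 24 pairs across genotypes and 3 of 12 between organs). That test included the library labelled pxy root replicate 2 and WT shoot replicate 2, which could hide a pairing, so it does not exclude one. Without the libraries labelled pxy root replicate 2 and 41-OX root replicate 4 the root counts were 8, 1277 and 1982. Leaving out 1 library gave 0 to 8, 39 to 1332 and 80 to 1983 in roots and 120 to 379, 4870 to 6235 and 4177 to 5890 in shoots. Counts of 0 for pxy roots are by edgeR, beside 2375 genes at an unadjusted p under 0.05 and 20 by DESeq2.

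Without the library labelled pxy root replicate 2 the root counts were 8, 1332 and 1983: DESeq2 gave 96 for pxy; the replicate block 3 for pxy and 1136 for 41-OX against pxy; genes within 1.5-fold 2, 209 and 307; the 2-fold threshold 397 and 550 for the last 2 comparisons; and leaving out 1 further library 3 to 10, 859 to 2470 and 1247 to 2565.

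For root minus shoot (1 gene for pxy, 402 for 41-OX) DESeq2 gave 13 and 690, joining root and shoot by genotype and number 0 and 54, 3 libraries left out together (pxy root 2, 41-OX root 4 and WT shoot 2) 5 and 2949, and 1 library left out 1 to 5 and 89 to 3435. The block within organs gave 64 and the genes within 1.5-fold 67 for 41-OX.

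The 13 opposite genes in shoots became 2 by DESeq2, 8 with the block, 0 with all 24 libraries, 4 within 1.5-fold, 3 at 2-fold and 4 to 13 with 1 library left out. In roots the count of 0 became 1 without the library labelled pxy root replicate 2, also with 41-OX root replicate 4 left out, so the range over single libraries was 0 to 1. The 1 opposite gene without that library became 16 by DESeq2, 0 within 1.5-fold, 0 at 2-fold and 1 to 2 with 1 further library left out.

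The 18 lists called became 0 with an estimated correlation, 8 by fry (6 of them among the 18), 18 with DESeq2 size factors, 18 with the block, 22 without the 2 root libraries above and 16 to 24 with 1 library left out. Reversed medians, here of differences in log2 CPM, were those in pxy roots of the xylem list (0.0433 without the library labelled pxy root replicate 2, 0.0432 without both) and the root epidermis list (0.0488 and 0.0486), and in pxy shoots of the photosynthetic list (0.0176 without WT shoot replicate 2). With 1 library left out, the lowest values of these 3 medians were -0.444, -0.916 and -0.574. DESeq2 size factors moved the median of all genes by at most 0.0417 on the log2 scale, and the share of risen genes in 41-OX shoots from 47.8% to 55.3%. Of 1708 values of genes under other settings 1472 kept their call, 236 lost it and 0 reversed; of 2352 with 1 library left out 1956 kept it, 396 lost it and 0 reversed. In simulated data with known changes of 1.5-fold, 4.48% were recovered in pxy roots as labelled, 43.3% without the library labelled pxy root replicate 2 and 65.7% in pxy shoots, beside common dispersions of 0.133, 0.0241 and 0.00843. Depth was not tested apart from this spread.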

Other observations

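The test of the hypothesis near PXY was planned before the result was seen; the other values here were computed after it.

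Some loci differed between lines in both organs. AT2G06845 stood at 6.91 ± 0.981 CPM in WT roots and 5.70 ± 3.86 CPM in WT shoots (n = 4 each), with 0 counts in pxy and 41-OX shoots, at least 83.2-fold and 81.7-fold lower against a floor of 3 counts over the group. AT2G06590 had 169 counts in 41-OX roots and 320 in 41-OX shoots and 0 in WT of either organ. AT5G35935 stood at 18.7 ± 1.26 CPM in pxy shoots and 0.196 ± 0.141 CPM in 41-OX shoots. These loci include pseudogenes, and they were chosen after their values were seen.

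Root-specific genes stood at unequal shares of their root level in 41-OX shoots, computed on CPM without TMM scaling. Over 73 root-specific genes with at least 50 CPM in 41-OX roots, the excess over WT and pxy shoots had a median of 3.73% of the root level. EXPA18 reached 21.4%, RHS18 20.2%, FLA6 19.7%, RSL2 18.3%, GH9C1 16.9%, AT1G30870 14.9%, LRL3 13.4%, CYP718 12.2% and EXPA7 11.1%, the 9 largest shares, so they were chosen after their values were seen. No list of root hair genes was tested.

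A hypothesis was that sequence carried along with the pxy lesion may alter genes near PXY. Of 432 tested genes within 1 Mb of PXY, 10 changed in pxy shoots (2.31%, against 1.74% elsewhere; odds ratio 1.34, 95% interval 0.632 to 2.52; Fisher's exact test, two-sided, p = 0.350). A p above the threshold was set in advance to count against it, but the interval shows that this bound was wrong: an excess of up to 2.52 times is not excluded, so the question stays open.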
